A study of Mus musculus with 18 samples.

How the data were processed

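Liver RNA from 18 male C57BL/6J mice had been hybridised to Mouse430_2 Affymetrix arrays, 1 mouse per array and 6 arrays in each of 3 groups. The groups were the control diet AIN93G, a Western-style diet (20% butter, 1% soy oil and 0.15% cholesterol) and the same diet with 0.05% quercetin, each fed for 20 weeks. Per the labels, RNA was purified on columns, copied by 1-cycle cDNA synthesis and labelled with biotin. The labels also give 3 mice per cage and 10 groups of 6 mice in the whole protocol, without saying which mice shared a cage. Arrays of the control diet with quercetin were not analysed here.

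The deposited values are intensity values on a linear scale, 1 signal per probe set. The steps by which the authors derived them from the scans, and any normalization, are not given in the sources used here. The table held 45101 probe sets on each array, with values from 0.0118 to 12323.2 and 0 missing. The medians of the arrays ran from 12.7 to 23.2 and the trimmed means from 67.2 to 102.5, so no common level had been set between arrays. Of the probe sets, 64 were spike-in and quality controls. No genome build was used, so no coordinates are given.

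The other 45037 probe sets were converted to log2(value + 16) and quantile normalized. Every fold given is thus a ratio of value + 16, which for dim genes is smaller than the ratio of the signals. The plan had been to use the values as deposited. Quantile normalization replaced them as the main setting once the distributions of the arrays were seen to differ, and before any test was run. The values as deposited were kept as an alternative and are reported beside it. Of these 45037 probe sets, 34945 were paired with exactly 1 gene symbol, 932 with several and 9160 with none. For 34741 of the first kind the symbol could be checked against a second table by gene identifier, and it was the same for all 34741. The brightest probe set stood for each of 18193 genes. Genes with a mean under the 25th percentile (log2 4.564) were left out as dim, which removed 4548 and left 13645.

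Control arrays 4 and 5 were far more alike than any other pair (correlation 0.999669 on the linear scale, where the next highest pair had 0.995938). They were averaged and counted as 1 sample, numbered 4-5, which left 17 samples with n = 5 for the control group. The plan had counted every array as a separate sample, and this averaging was chosen after the arrays had been seen. The mice were taken as the replicates. Mice of the same cage may be alike, and since the cages are not given, the cage could not be modelled. The number of mice limits the precision of each value: the 95% interval of a log2 difference had a median width of 0.244 to either side for a comparison with the control group and 0.233 between the groups on the Western-style diet.

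Genes were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 17 samples, followed by contrasts and eBayes with default settings. All tests were two-sided. P values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, and an adjusted p under 0.05 was called a change. Every p given for a single gene is from this moderated t test, also where a sample was left out. Gene lists with at least 5 measured members were tested with camera, a competitive test of limma, at a preset correlation of 0.01 between genes. They were tested again with the correlation estimated from the data, and with the self-contained test fry. P values of lists were adjusted over the 25 lists of a comparison. The counts of members use the threshold over all genes, and a further count adjusts over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

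The comparisons, tests, gene lists, cell type marker lists, alternatives and rule for naming genes were chosen before the data were examined, save those said here or in the closing section to have been added or changed. The rule named, in each comparison, up to 10 genes with the largest increase and 10 with the largest decrease among those that changed, with at least 5 of the first group's 6 mice on the changed side of the second group's mean. Where no gene changed it named the 5 with the smallest unadjusted p in each direction. Of each list it named up to 4 members with the smallest p for the Western-style diet against the control diet and up to 2 for quercetin within the Western-style diet. The report gives a part of the genes so named, and outside the closing section no gene in it falls outside the rule.

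Whether the quercetin change ran against the diet change was measured over genes with shared samples, with the Western samples split 3 and 3 in 20 ways, in 100 simulations without differences, and over 100 relabellings of the 12 Western mice. Each count of genes or lists was compared with 100 splits of the same samples (seed 12, the real split included), and with 100 that kept the samples numbered 1 to 3 and 4 to 6 apart. The calling was tested on simulated data in which 200 of 13645 genes were changed in each of 10 runs. Changes of 1.5-fold were found in 70.8%, 70.0% and 68.0% of cases, and changes of 2-fold in 96.4%, 96.0% and 93.8%, for the Western-style diet against the control diet, quercetin within the Western-style diet, and the Western-style diet with quercetin against the control diet. Mean false calls per run were 9.3, 10.5 and 9.

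The alternatives were the values as deposited, centred array medians, no filter on dim genes or one at the 50th percentile, the mean of a gene's probe sets, no probe sets with names ending in _x_at or _s_at, and a pseudocount of 1. Others were an intensity trend, robust variances, array weights, a block for the replicate number, only the 2 groups compared, all probe sets, an adjusted p under 0.01, a fold of at least 1.5, and leaving out each sample in turn. Control arrays 4 and 5 as 2 samples, as the plan had counted them, became an alternative once they were averaged. Added after the data were seen were the samples numbered 1 to 3 and 4 to 6 as a block or taken apart, the actin 3'/5' ratio of each sample as a covariate, and exact permutation of per-mouse list means, over all mice or within these sets of numbers. Probe sets without exactly 1 symbol were not part of the comparisons.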

Results

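Liver RNA of male C57BL/6J mice was measured on Affymetrix Mouse Genome arrays, on which each transcript is read by 1 or more sets of short probes. The mice had been fed for 20 weeks on 1 of 3 diets. The control diet was AIN93G, a purified rodent diet. The Western-style diet had 39.9% of its energy from fat, 34.0% from sucrose and 0.15% cholesterol. The last was the Western-style diet with 0.05% quercetin, a flavonol found in many edible plants. Each group had 6 arrays, each with the RNA of 1 mouse per the labels. Brightness was taken as the trimmed mean signal of an array, in the deposited intensity units. Control arrays 1 to 6 had trimmed means of 76.0, 81.3, 72.2, 80.6, 76.8 and 67.2, a mean of 75.1 ± 5.58 (SD, n = 5, with arrays 4 and 5 averaged). Western arrays 1 to 6 had 98.8, 80.7, 84.8, 102.5, 94.0 and 86.9, a mean of 91.3 ± 8.51 (SD, n = 6). Arrays 1 to 6 of the quercetin group had 95.1, 93.9, 82.9, 96.0, 87.0 and 92.5, a mean of 91.2 ± 5.17 (SD, n = 6). Control arrays 4 and 5 were nearly identical. Over 2645 bright probe sets their log2 differences had an SD of 0.0469, where the next closest of all 153 pairs of arrays had 0.155. The other control pairs lay between 0.175 and 0.425. These 2 arrays were averaged and counted as 1 sample, so the control group entered every test with n = 5 and the other groups with n = 6. After quantile normalization and a filter on dim genes, 13645 genes were compared, and the number of arrays limits the precision of each value.

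The Western-style diet was compared with the control diet to describe what the diet itself does to the liver. Cidea, which encodes a protein that helps lipid droplets fuse and grow, rose from a log2 level of 5.48 ± 0.46 (SD, n = 5) in the control group to 10.18 ± 0.23 (SD, n = 6) in the Western group, a 25.9-fold increase (adjusted p = 3.53e-10, limma). Cidec, a second protein of that family, rose 8.64-fold (log2 change 3.11 ± 0.22, SE; adjusted p = 1.88e-07). Gpnmb, a membrane glycoprotein abundant in lipid-laden macrophages, rose 5.62-fold, and Col3a1, a chain of fibrillar collagen, rose 3.63-fold (log2 change 1.86 ± 0.25, SE; adjusted p = 0.000277). In the opposite direction, Sqle, which encodes the squalene epoxidase of cholesterol synthesis, fell from 8.13 ± 0.66 (SD, n = 5) to 6.29 ± 0.69 (SD, n = 6) on the log2 scale, a 3.58-fold decrease (adjusted p = 0.00256). In total 1180 genes changed, 749 of them higher and 431 lower on the Western-style diet, and 74 of the former and 23 of the latter differed at least 2-fold.

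The largest increases after Cidea were those of Ly6d, which encodes a lipid-anchored surface protein (9.55-fold), Cidec, Gpnmb, Lcn2, a siderophore-binding acute phase protein (5.12-fold), and Mmp12, the macrophage elastase (5.05-fold). They were followed by Cbr3, a carbonyl reductase (4.41-fold), Gstm3, a glutathione transferase (4.15-fold), Adgrv1, an adhesion receptor (3.93-fold), and Lpl, lipoprotein lipase (3.81-fold). Among the largest decreases, Hamp2, a hepcidin gene, was 3.47-fold lower. Clec2h, a lectin gene, was 3.09-fold lower, and Idi1, which encodes the isomerase that makes the activated isoprene units of sterol synthesis, was 2.86-fold lower. Rdh16f2, a retinol dehydrogenase gene, was 2.84-fold lower with a narrow spread (9.89 ± 0.16 against 8.39 ± 0.22, SD, n = 5 and 6; adjusted p = 1.43e-05). Etnppl, an enzyme of phosphoethanolamine breakdown, Cela1, an elastase, and Enho, which encodes the secreted peptide adropin, were 2.66-fold, 2.48-fold and 2.42-fold lower. Hsd3b5, a steroid dehydrogenase that is normally male-biased in mouse liver, was 7.56-fold lower (adjusted p = 0.0205), but its adjusted p was 0.0577 without control 6, 0.0503 without western 1 and 0.0513 without western 4. Slc22a7, an organic anion transporter, was 2.69-fold lower (adjusted p = 0.0204), and its adjusted p was 0.0546 without control 3 and 0.0621 without control 6.

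Genes of lipid storage and of sterol synthesis moved in opposite directions. Of 21 measured members of the lipid droplet and fat storage list, 12 rose, 0 fell and 9 did not pass, with 13 changed when adjusted over the list alone and a median log2 change of 0.41. Besides Cidea, Cidec and Lpl, they included Mogat1, an acyltransferase of triglyceride synthesis (2.06-fold), and Apoa4, an apolipoprotein of triglyceride-rich particles (1.94-fold). This list was higher by camera (adjusted p = 5.27e-14), and it alone of the 25 lists kept its call in this comparison with an estimated correlation (adjusted p = 0.0064). Of 20 members of the cholesterol synthesis and uptake list, 0 rose, 13 fell and 7 did not pass, and 17 changed when adjusted over the list alone. The median log2 change was −0.65 and all 20 had a negative sign. Besides Sqle and Idi1, the sterol enzymes Msmo1, Tm7sf2 and Cyp51 fell by 1.22, 1.14 and 1.07 on the log2 scale. Camera placed the list lower with an adjusted p = 7.31e-16, and the adjusted p was 0.0805 with an estimated correlation. Of 19 fatty acid synthesis genes 3 rose, with 5 changed when adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.0663; with an estimated correlation adjusted p = 0.523). The list passed camera on the higher side with no filter on dim genes (0.0403), with the numbers 1 to 3 and 4 to 6 as a block (0.0328) and with a block for each number (0.0309). Among its members Scd2, a stearoyl-CoA desaturase, rose 2.97-fold. Ehhadh, of peroxisomal oxidation, rose 1.31-fold. Of the 26 fatty acid oxidation genes and PPAR-alpha targets 4 rose and 1 fell, with 7 changed when adjusted over the list alone and a median of 0.10 (camera adjusted p = 0.0152; with an estimated correlation adjusted p = 0.282). This camera call was lost on the values as deposited (adjusted p = 0.111), with array medians centred (adjusted p = 0.171), without control 1 (adjusted p = 0.0692) and without control 3 (adjusted p = 0.0572).

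Matrix genes rose together with markers of macrophages and of stellate cells, the collagen-making cells of the liver sinusoid. Of 15 fibrosis genes 11 rose and 0 fell, with 13 changed when adjusted over the list alone and a median log2 change of 0.67. Col1a1 and Col1a2, the chains of type I collagen, rose 3.45-fold and 2.07-fold. Camera gave the fibrosis list an adjusted p = 5.27e-14, and with an estimated correlation the adjusted p was 0.0898. Of 22 macrophage and Kupffer cell markers 14 rose and 0 fell, with 19 changed when adjusted over the list alone and a median of 0.70. Lgals3, a galectin of activated macrophages, rose 3.32-fold, and Lyz2, lysozyme of myeloid cells, rose 2.65-fold. The marker list had a camera adjusted p = 5.95e-14 and, with an estimated correlation, an adjusted p = 0.152. Of 10 stellate cell markers 4 rose and 0 fell, with 5 changed when adjusted over the list alone and a median of 0.40 (camera adjusted p = 1.13e-05; with an estimated correlation adjusted p = 0.13). Rgs5 and Pdgfrb, both also found in pericytes, rose 1.74-fold and 1.62-fold, and Dcn, a matrix proteoglycan, rose 1.55-fold; Col1a1 stands in both this list and the fibrosis list. Of 10 hepatocyte markers 0 rose and 2 fell, with 3 changed when adjusted over the list alone and a median of −0.11 (camera adjusted p = 0.00676; with an estimated correlation adjusted p = 0.152). Of 10 endothelial cell markers 2 rose and 0 fell, with 3 changed when adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.0105; with an estimated correlation adjusted p = 0.212).

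Inflammatory, acute phase, antioxidant and cell cycle genes also held members that rose. Of 14 inflammatory signalling genes 4 rose and 0 fell, with 6 changed when adjusted over the list alone and a median of 0.35 (camera adjusted p = 0.000533; with an estimated correlation adjusted p = 0.244). Ccl2, a chemokine that attracts monocytes, rose 2.08-fold and Icam1, an adhesion molecule, rose 1.62-fold. Of 17 acute phase genes 5 rose and 0 fell, with 8 changed when adjusted over the list alone. Orm3 and Orm2, which encode acid glycoproteins, rose 3.38-fold and 2.92-fold. The acute phase list had a median of 0.10 and a camera adjusted p = 0.0301, with an estimated correlation an adjusted p = 0.412. On the values as deposited and with array medians centred its median relative to all genes was −0.016 and its camera call was lost (adjusted p = 0.304 and 0.324). The call was also lost without probe sets ending in _x_at or _s_at (0.0653), with only the 2 groups compared (0.0631), and without control 4-5 (0.0592), control 6 (0.0589) or western 3 (0.0651). Of 23 antioxidant and glutathione genes 8 rose and 0 fell, with 12 changed when adjusted over the list alone and a median of 0.38 (camera adjusted p = 7.97e-07; with an estimated correlation adjusted p = 0.0926). Ephx1, the microsomal epoxide hydrolase, rose from 10.78 ± 0.10 (SD, n = 5) to 11.47 ± 0.06 (SD, n = 6), a 1.61-fold increase, and Gstm1 and Gpx4, a glutathione transferase and a glutathione peroxidase, rose 1.49-fold and 1.44-fold. Mcm6, of the replicative helicase, rose 1.75-fold. Of 15 proliferation genes 3 rose and 0 fell, with 6 changed when adjusted over the list alone and a median of 0.43 (camera adjusted p = 2.13e-05; with an estimated correlation adjusted p = 0.178). Of 15 interferon response genes 4 rose and 0 fell, with 4 changed when adjusted over the list alone and a median of 0.12 (camera adjusted p = 0.0105; with an estimated correlation adjusted p = 0.353). Oasl2 and Oas1a, of the oligoadenylate synthetase family, rose 1.88-fold and 1.37-fold. The interferon list had a camera adjusted p = 0.0526 without control 2.

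In the lists of transport, drug metabolism and energy genes most members did not pass, as for all genes compared, of which 8.65% changed. Of 21 genes of bile acid synthesis and sterol transport 4 rose and 1 fell, with 6 changed when adjusted over the list alone and a median of −0.16 (camera adjusted p = 0.499; with an estimated correlation adjusted p = 0.748). Abcc3, an efflux transporter of the sinusoidal membrane, rose 1.47-fold, and Slc10a1, the bile acid uptake transporter, was 1.56-fold lower. Cyp1a2, a cytochrome P450, was 1.80-fold lower and Sult1a1, a phenol sulfotransferase, 1.49-fold lower. Of 18 drug metabolism genes 0 rose and 2 fell, with 2 changed when adjusted over the list alone and a median of −0.17 (camera adjusted p = 0.0663; with an estimated correlation adjusted p = 0.27). Of 15 glucose and insulin genes 1 fell, with 2 changed when adjusted over the list alone and a median of −0.14 (camera adjusted p = 0.0414; with an estimated correlation adjusted p = 0.13). The camera call was lost with the mean of a gene's probe sets (0.0674) and without probe sets ending in _x_at or _s_at (0.0698). It was also lost without control 4-5 (0.0804), control 6 (0.0589), western 1 (0.0543), western 2 (0.0564) or western 6 (0.05). Of 29 oxidative phosphorylation genes 2 fell, with 0 changed when adjusted over the list alone and a median of −0.041 (camera adjusted p = 0.0211, and 0.111 on the values as deposited; with an estimated correlation adjusted p = 0.244). The complement gene C8b was 1.93-fold lower. With Hsd3b5 it made up the 2 of 12 male-biased liver genes that fell, with 4 changed when adjusted over the list alone and a median of −0.13 (camera adjusted p = 0.0748; with an estimated correlation adjusted p = 0.56). Hao2, a hydroxyacid oxidase, was 2.26-fold lower. It was the 1 of 8 female-biased genes that fell, with 1 changed when adjusted over the list alone and a median of −0.52 (camera adjusted p = 0.0663; with an estimated correlation adjusted p = 0.353). On the values as deposited camera called drug metabolism, male-biased and female-biased genes lower (adjusted p = 0.00064, 0.000196 and 0.000196) and the circadian clock list lower as well (adjusted p = 0.0281). The first 3 of these were also called lower with array medians centred (0.00573, 0.00334 and 0.00693) and with a block for each number (0.0386, 0.0377 and 0.0275).

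In 4 lists no member passed, and 0 changed when adjusted over the list alone. They were 18 genes of the unfolded protein and amino acid response (median −0.083, camera adjusted p = 0.338), 15 circadian clock genes (−0.10, 0.358), 5 T cell markers (−0.10, 0.499) and 6 neutrophil markers (0.26, 0.162). With an estimated correlation their adjusted p were 0.742, 0.58, 0.56 and 0.395. Of 7 B cell markers 1 rose, Cd74, the class II invariant chain that macrophages also make (1.79-fold), and 1 fell, with 2 changed when adjusted over the list alone. The list's median was −0.088 and its mean 0.027 (camera adjusted p = 0.732; with an estimated correlation adjusted p = 0.782). Lists with under 5 measured members were not tested: cholangiocyte (4 members, median 0.27), erythroid (2, −0.14), adipocyte (3, −0.24), skeletal muscle (4, −0.092) and exocrine pancreas markers (3, −0.24), of which the last held 1 passing gene, Cela1.

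**Figure D1:**
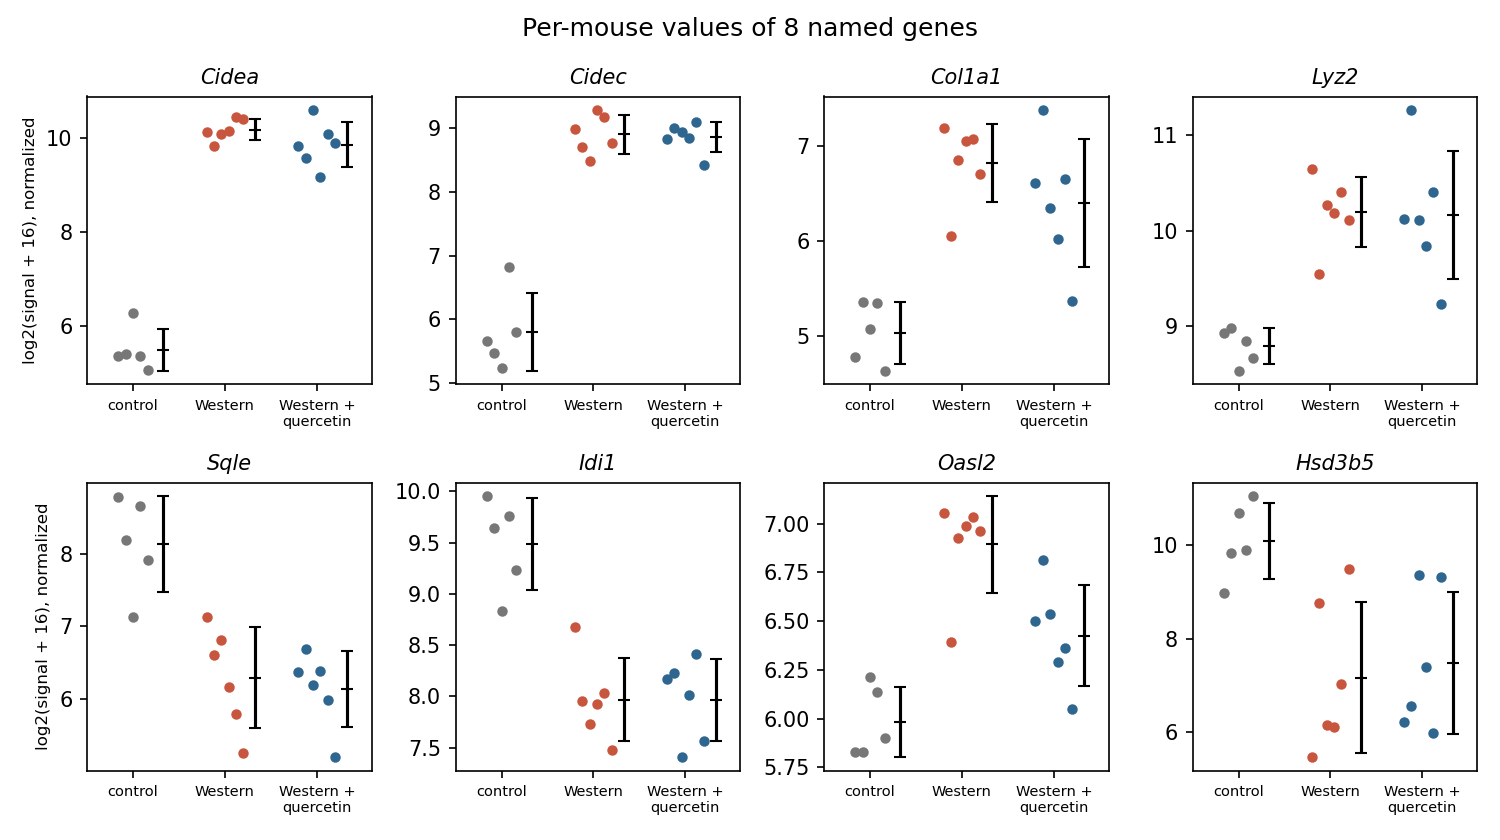
Log2 level per sample of named genes in the control (n = 5), Western (n = 6) and Western with quercetin (n = 6) groups, with each group's mean and SD. Cidea lies near 5.48 in the control group and near 10.18 and 9.86 in the other groups.

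The comparison rested on limma, fitted to all 17 samples of the 3 groups with Benjamini-Hochberg adjustment over the 13645 genes, and 3181 genes had an unadjusted p under 0.05, where 682.25 would be expected without any difference. Scaling set the balance of directions. On the values as deposited the median of all genes was 0.22 higher (log2) in the Western group and 3725 genes passed (3641 higher, 84 lower). With array medians centred 1284 passed (1108 higher, 176 lower). The count fell to 748 without western 4, 773 without control 6 and 784 without western 5, and it was 88 within the samples numbered 1 to 3 and 296 within those numbered 4 to 6. The arrays also differed in the 3'/5' ratio of actin, a measure of RNA integrity, at 0.69 ± 0.06 (SD, n = 5) in the control and 0.54 ± 0.11 (SD, n = 6) in the Western group (log2; exact p = 0.0325). The ratio of Gapdh differed by −0.014 (exact p = 0.517) and the 18S signal by 0.85 (exact p = 0.123). With the actin ratio as a covariate 223 genes passed, of which 210 were among the 1180. All 1180 kept their sign and a median of 90.0% of their change, the median standard error was 0.142 in place of 0.116, and no gene was called for the ratio itself, but the ratio and the diet overlap, so a part of the count that follows RNA integrity is not excluded. Camera with its preset correlation passed 15 of the 25 lists here, and a median of 5 lists on other splits of the same samples, so its small p values overstate the evidence. The test fry, which is not relative to the other genes, called 14 lists (smallest adjusted p = 5.56e-07), 13 of them also called by camera. Among them were cholesterol synthesis (0.000242), fibrosis (0.000281), glucose and insulin (0.000783) and macrophage genes (0.00353), while acute phase (0.0582) and interferon response genes (0.0696) were called by camera alone. Drug metabolism (0.0446) was called by fry alone.

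**Figure D2:**
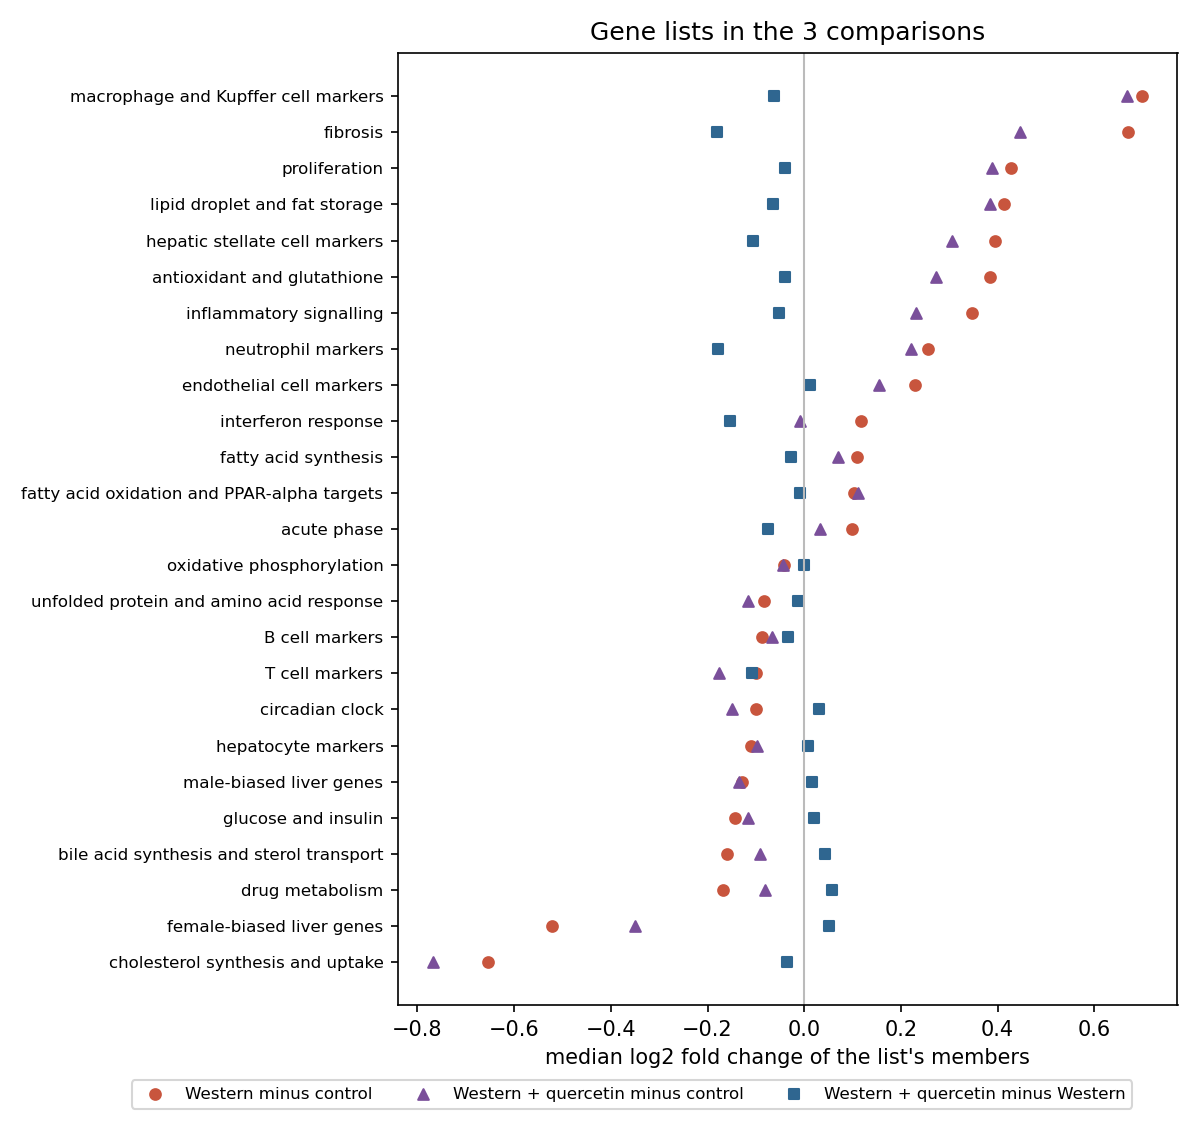
Median log2 change of the measured members of each of the 25 gene lists, in the 3 comparisons. Against the control diet the medians run from −0.65 to 0.70 for the Western-style diet and from −0.77 to 0.67 with quercetin, and between these 2 groups from −0.18 to 0.058.

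Quercetin within the Western-style diet was compared with that diet alone, which is the question in the title of the series. None of the genes that the diet had changed most passed here. Cidea was at 9.86 ± 0.48 (SD, n = 6) with quercetin against 10.18 ± 0.23 (SD, n = 6) without, a log2 difference of −0.32 with a 95% interval of −0.76 to 0.12 (unadjusted p = 0.146, limma). Cidec differed by −0.05 (95% interval −0.48 to 0.39) and Sqle by −0.16 (−0.83 to 0.52). Col1a1 and Col3a1 had differences of −0.42 (−0.97 to 0.12) and −0.36 (−0.86 to 0.14), and Gpnmb one of −0.09 (−0.72 to 0.54). In the interferon response list, whose members are induced by type I interferon, Oasl2 stood at 6.42 ± 0.26 (SD, n = 6) with quercetin and 6.89 ± 0.25 (SD, n = 6) without, a difference of −0.47 (95% interval −0.74 to −0.20, unadjusted p = 0.0019, adjusted p = 1).

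With limma, 0 of the 13645 genes differed between the groups, the smallest adjusted p was 1, and 392 genes had an unadjusted p under 0.05, fewer than the 682.25 expected without any difference. The genes with the smallest unadjusted p, none of which passed, were Zbtb8b, a zinc finger gene (0.63, 95% interval 0.32 to 0.94, unadjusted p = 0.000409, limma), Plekhg4 (0.38), Kctd7 (0.45), Cenpq, of the centromere (0.40), and Cul5, a cullin (0.31), on the higher side. On the lower side they were Ercc6, a DNA repair gene (−0.36, 95% interval −0.51 to −0.21, unadjusted p = 0.000104), Nobox (−0.81), Tmem121b (−0.49), Zfp775 (−0.27) and Eda (−0.54). Several of these, Nobox among them at 4.53 ± 0.29 (SD, n = 6) with quercetin, lay near the level of log2 4.56 below which genes were left out as dim. The count was also 0 on the values as deposited (316 genes with an unadjusted p under 0.05), with array medians centred (383), and within the samples numbered 1 to 3 (400) or 4 to 6 (1046). The last exceeds the 682.25 expected. Of the 10 ways to part these 6 mice 3 and 3, 2 gave as many, the real one included. So few ways could not have excluded chance, and the excess stays open. The 95% interval of a gene's difference had a median width of 0.233 log2 units to either side, and in data with planted changes 70.0% of genes changed 1.5-fold and 96.0% of those changed 2-fold were found in this comparison. Those data had independent noise for each gene and also held 3-fold changes. Their shares need not hold for the real comparison.

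Of the 25 lists, 3 were lower with quercetin by camera, and in none of them did a member pass over all genes. In the interferon response list all 15 members had a negative sign, with a median of −0.15 and 1 member changed when adjusted over the list alone (camera adjusted p = 5.36e-08; with an estimated correlation adjusted p = 0.45). Besides Oasl2, Ifit3 differed by −0.31 (95% interval −0.56 to −0.07) and Mx1 by −0.23 (−0.41 to −0.04). The per-mouse means of this list differed by −0.20 (exact two-sided permutation p = 0.0455 over the 924 splits of 12 mice, 0.957 after adjustment over the 25 lists). This difference was 0.0039 in the samples numbered 1 to 3 and −0.40 in those numbered 4 to 6, and with permutation kept within these sets p was 0.06 (0.908 adjusted). With so few possible splits, a single list could not pass either permutation test after adjustment over the 25 lists. Macrophage and Kupffer cell markers had a median of −0.063 (camera adjusted p = 0.476), and of −0.24 (8.8e-06) without quercetin 2. The fibrosis list had 14 of 15 members with a negative sign, a median of −0.18 and 0 members changed when adjusted over the list alone (camera adjusted p = 0.00169; with an estimated correlation adjusted p = 0.777). Its camera call was lost without western 1 (0.0748) and without quercetin 6 (0.346). Its per-mouse means differed by 0.025 in the samples numbered 1 to 3 and by −0.36 in those numbered 4 to 6. Stellate cell (0.082 and −0.25), macrophage (0.18 and −0.28) and inflammatory signalling lists (0.17 and −0.30) differed likewise in these sets, while other lists, given below, went the other way. The acute phase list had 14 of 17 members with a negative sign, a median of −0.075 and 0 changed when adjusted over the list alone (camera adjusted p = 0.0184; with an estimated correlation adjusted p = 0.777). Its call was lost without western 3 (0.531), western 4 (0.0551), quercetin 1 (0.0914) or quercetin 6 (0.109), and its per-mouse means differed by −0.22 in the samples numbered 1 to 3 and by −0.092 in those numbered 4 to 6. Between these sets the largest contrasts in p were those of cholesterol synthesis (−0.27 and 0.14, exact p = 0.02) and fatty acid synthesis (−0.30 and 0.22, 0.02), ahead of interferon response (0.045), and none passed after adjustment over the 25 lists (smallest 0.208). Here too the number of splits let no single list pass alone. Leaving out quercetin 2 made 8 lists pass and leaving out quercetin 6 left 1. The test fry, which asks whether a list's genes move on balance in 1 direction, called no list here (smallest adjusted p = 0.706). Other splits of the 12 mice passed a median of 4 lists by camera.

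In the other 22 lists no member passed over all genes, 0 changed when adjusted over the list alone, and camera called none. The medians were below 0 for cholesterol synthesis and uptake (−0.035, camera adjusted p = 0.375), fatty acid synthesis (−0.027, 0.622), fatty acid oxidation and PPAR-alpha targets (−0.0078, 0.612), lipid droplet and fat storage (−0.064, 0.153), antioxidant and glutathione genes (−0.040, 0.622) and inflammatory signalling (−0.052, 0.476). They were also below 0 for the unfolded protein and amino acid response (−0.014, 0.859) and proliferation (−0.039, 0.656). Besides the macrophage markers given above, the cell type medians below 0 were those of stellate cells (−0.11, 0.298), T cells (−0.11, 0.612), B cells (−0.034, 0.984, with a mean of 0.0022) and neutrophils (−0.18, 0.682). Medians above 0 were found for bile acid synthesis and sterol transport (0.043, camera adjusted p = 0.298), drug metabolism (0.058, 0.262), glucose and insulin genes (0.020, 0.36) and oxidative phosphorylation (0.00048, 0.682). The same held for the circadian clock (0.031, 0.991), male-biased (0.016, 0.741) and female-biased genes (0.051, 0.612), hepatocyte markers (0.0070, 0.298) and endothelial markers (0.012, 0.915, with a mean of −0.018). With an estimated correlation the adjusted p of these 22 lists ran from 0.777 to 0.994. Without western 2 or quercetin 3 the lipid droplet list passed camera on the lower side (adjusted p = 0.0194 and 0.0395), and without western 6 the cholesterol list did (0.0122). Without quercetin 2 the macrophage (8.8e-06), inflammatory signalling (0.00182) and stellate cell lists (0.0172) passed on the lower side, and bile acid (0.00439) and drug metabolism genes (0.016) on the higher.

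The Western-style diet with quercetin was compared with the control diet to see which differences from the control remained with the compound. Cidea was 20.8-fold higher than in the control group (9.86 ± 0.48 against 5.48 ± 0.46, SD, n = 6 and 5; adjusted p = 1.2e-09, limma) and Cidec was higher by 3.06 on the log2 scale. Among the sterol enzymes, Sqle was 3.99-fold lower, and Cyp51 fell by 1.38 and Tm7sf2 by 1.06 on the log2 scale. Gpx6, a glutathione peroxidase gene, fell by 1.30 (adjusted p = 0.000265), and Rdh16f2 fell by 1.38. In total 738 genes changed, 468 higher and 270 lower, of which 57 and 20 differed at least 2-fold, and 2718 had an unadjusted p under 0.05. Hsd3b5 differed by −2.61 (adjusted p = 0.0466), but its call was lost with no filter on dim genes (0.0621), with a pseudocount of 1 (0.079) and in 11 of the settings that left out 1 sample, with adjusted p of up to 0.116 without control 6. Hamp2 differed by −1.34 (adjusted p = 0.0256), but its call was lost with the mean of all probe sets (−0.56, 0.0787), with only the 2 groups compared (0.0614), and without control 2 (0.0727), quercetin 1 (0.0513) or quercetin 2 (0.0611). Slc22a7 differed by −1.52 (adjusted p = 0.0196, and 0.0546 without control 3 and 0.0609 without control 6).

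In the lists, 13 of 20 cholesterol synthesis and uptake genes fell and 0 rose, with 18 changed when adjusted over the list alone and a median of −0.77 (camera adjusted p = 1.46e-19; with an estimated correlation adjusted p = 0.0395). Of 21 lipid droplet and fat storage genes 11 rose and 0 fell, with 11 changed when adjusted over the list alone and a median of 0.39 (camera adjusted p = 3.6e-13; with an estimated correlation adjusted p = 0.00863). These were the 2 lists whose calls held with an estimated correlation in this comparison. Macrophage and Kupffer cell markers rose in 10 of 22 members, with 17 changed when adjusted over the list alone and a median of 0.67 (camera adjusted p = 3.59e-14; with an estimated correlation adjusted p = 0.183). Beside them fibrosis genes had 7 of 15 higher, 12 changed when adjusted over the list alone and a median of 0.45 (camera adjusted p = 7.46e-12; with an estimated correlation adjusted p = 0.113). Stellate cell markers had 4 of 10 higher, 5 changed when adjusted over the list alone and a median of 0.31 (camera adjusted p = 5.71e-05; with an estimated correlation adjusted p = 0.183). Of 23 antioxidant and glutathione genes 5 rose, with 11 changed when adjusted over the list alone and a median of 0.27 (camera adjusted p = 7.04e-07; with an estimated correlation adjusted p = 0.113). Of 15 proliferation genes 2 rose, with 5 changed when adjusted over the list alone and a median of 0.39 (camera adjusted p = 3.81e-05; with an estimated correlation adjusted p = 0.238). Inflammatory signalling had 3 of 14 higher, 5 changed when adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.00236; with an estimated correlation adjusted p = 0.312), and its camera call was lost with the dim filter at the 50th percentile (0.0859). Endothelial markers had 1 of 10 higher, 1 changed when adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.00986; with an estimated correlation adjusted p = 0.238).

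Camera also placed hepatocyte markers lower, with 0 of 10 members passing, 0 changed when adjusted over the list alone and a median of −0.098 (adjusted p = 0.0298; with an estimated correlation adjusted p = 0.238). That call was lost without probe sets ending in _x_at or _s_at (0.0739) and without control 3 (0.0836), quercetin 1 (0.0532) and quercetin 3 (0.0581). Fatty acid oxidation and PPAR-alpha targets had 3 of 26 higher, 4 changed when adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.0328; with an estimated correlation adjusted p = 0.376). This was lost on the values as deposited (0.196), with array medians centred (0.308), with control 4 and 5 as 2 samples (0.113) and without control 1 (0.148), control 3 (0.125), quercetin 3 (0.0923) or quercetin 5 (0.0593). Oxidative phosphorylation had 1 of 29 lower, 0 changed when adjusted over the list alone and a median of −0.045 (camera adjusted p = 0.0328; with an estimated correlation adjusted p = 0.298), and this was lost on the values as deposited (0.109), with only the 2 groups compared (0.0503) and without control 1 (0.0509), quercetin 2 (0.1) or quercetin 3 (0.0592). The remaining 13 lists were not called by camera. They were fatty acid synthesis (3 of 19 higher, 5 adjusted over the list alone, median 0.069), and bile acid synthesis and sterol transport (4 higher and 1 lower of 21, 6 adjusted over the list alone, median −0.091, though the test pointed up). In the same order of values came drug metabolism (1 of 18 lower, 1 adjusted over the list alone, −0.081), acute phase (3 of 17 higher, 5 adjusted over the list alone, 0.032), glucose and insulin (0 of 15, 0 adjusted over the list alone, −0.12), and the unfolded protein and amino acid response (0 of 18, 0, −0.12). The rest were the circadian clock (0 of 15, 0, −0.15), male-biased genes (2 of 12 lower, 2, −0.13), female-biased genes (1 of 8 lower, 1, −0.35), interferon response (0 of 15, 2, −0.0084 with a mean of 0.0013), markers of T cells (0 of 5, 0, −0.18), B cells (1 higher and 1 lower of 7, 2, −0.066 with a mean of 0.030) and neutrophils (0 of 6, 0, 0.22). Their camera adjusted p ran from 0.136 for male-biased genes to 0.953, and with an estimated correlation from 0.238 to 0.976. On the values as deposited camera called 7 of them lower: the circadian clock (0.0109), drug metabolism (0.00572), female-biased (0.000287) and male-biased genes (6.57e-05), glucose and insulin (0.0163), T cells (0.0264) and the unfolded protein and amino acid response (0.0151). Of these drug metabolism (0.0491), female-biased (0.0319) and male-biased genes (0.00371), glucose and insulin (0.0347) and T cells (0.0438) were also called with array medians centred, female-biased genes without control 6 (0.034) or quercetin 4 (0.0417) and male-biased genes without control 2 (0.0356) or quercetin 6 (0.027).

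The genes called in both comparisons with the control diet numbered 420 on the higher and 210 on the lower side, where independent calls would share 25.7 and 8.53, and 0 genes were called in opposite directions. Both comparisons use the same control samples, which alone makes them alike. Over genes, which are not independent replicates, their log2 changes correlated at 0.902. The correlation was 0.545 in simulations without differences that shared the control samples. It was 0.610 when the control samples were split so that none was shared. The 0.545 is no measure for this split value, whose changes share no sample and rest on fewer control samples each. The covariance was 0.061 with all control samples, 0.011 in the simulations and 0.049 on average over the splits. Whether the quercetin change ran against the diet change was tested with the Western samples split so that none was shared. The correlation over genes was then −0.10 on average over 20 splits (−0.27 to 0.14), and of the mean of 445 diet-changed genes per split 64.1% had the opposite sign (36.2% to 88.3%). With all Western samples in both changes the correlation was −0.39, where simulations without differences gave −0.48. The simulations hold no diet change, and a diet change by itself weakens this correlation, so these values cannot be compared. The covariance, which is not scaled in this way, was −0.013 observed and −0.0094 on average in the simulations. Relabelling the 12 Western mice gave a covariance as low as the observed −0.013 in 21 of 100 relabellings.

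This comparison with the control diet used the same limma fit, and the difference between its count and the diet's was not tested beyond the direct comparison of quercetin with the Western-style diet. On the values as deposited 3255 genes passed (3197 higher, 58 lower) and with array medians centred 679 (575 higher, 104 lower), with the median of all genes 0.22 higher (log2) as deposited. The count fell to 460 without control 6, 479 without quercetin 2 and 481 without quercetin 5. It was 224 within the samples numbered 1 to 3, 32 within those numbered 4 to 6, and 155 with the actin 3'/5' ratio as a covariate. With this covariate the 738 genes all kept their sign and a median of 91.7% of their change, and the median standard error was 0.139 in place of 0.116. Camera passed 12 lists, and a median of 5 on other splits of the same samples. The test fry called 12 (smallest adjusted p = 2.54e-06), 10 of them also called by camera.

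**Figure D3:**
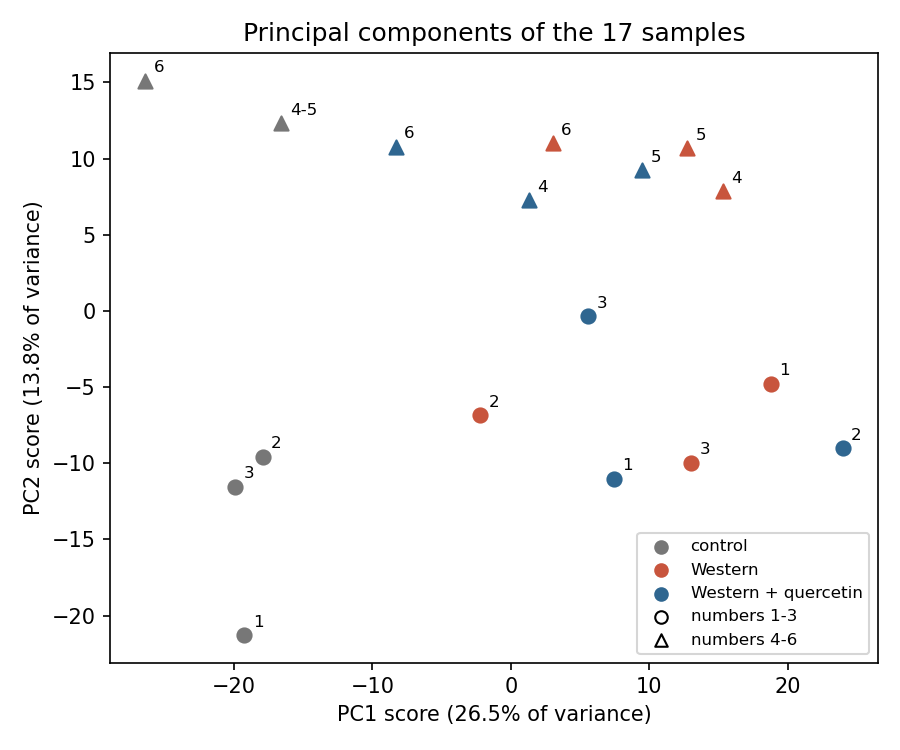
The first 2 principal components of the 17 samples over the 13645 genes, which hold 26.5% and 13.8% of the variance, with the group given by colour and the numbers 1 to 3 and 4 to 6 by symbol. The control samples lie apart from the 12 Western samples, which overlap with and without quercetin.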

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

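The tests on the control arrays' brightness and on the interferon list, also within the sets of numbers, those on RNA integrity, time of day and cages, the split tests of the quercetin gene count and of the opposition, and all splits within the sets of numbers were chosen only after the result was seen.

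Among 198 groups of values of 66 genes, 17 held 1 sample far from the others, by the gap to the nearest sample as a share of the group's range. With 18 groups of array measures, of which none did, chance flags about 1 in 20 groups, here 10.8. In the control group, sample 3 was highest for Cidea (6.26, others 5.05 to 5.39; share 0.716), and sample 1 for Mogat1 (6.71, others 6.11 to 6.25; 0.763) and Orm2 (9.14, others 7.91 to 8.05; 0.886). Control sample 6 was lowest for Gstm3 (7.98, others 8.90 to 9.18; 0.768) and Gstm1 (11.85, others 12.31 to 12.43; 0.795). In the Western group, sample 2 was lowest for Gpnmb (6.07, others 7.07 to 7.42; 0.741) and Oasl2 (6.39, others 6.93 to 7.05; 0.809). Western sample 3 was highest for Orm2 (10.95, others 9.11 to 9.77; 0.639) and Eda (5.73, others 5.15 to 5.22; 0.872) and lowest for Sult1a1 (10.23, others 10.79 to 11.04; 0.691).

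With quercetin, sample 2 was highest for Ephx1 (11.63, others 11.35 to 11.43; share 0.732) and Oas1a (7.59, others up to 7.16; 0.741) and lowest for Slc10a1 (10.81, others 11.47 to 11.73; 0.716). Sample 1 was highest for Mogat1 (7.61, others 7.12 to 7.28; 0.665) and lowest for Gpx6 (4.33, others 4.92 to 5.21; 0.665). Sample 3 was highest for Plekhg4 (5.09, others 4.74 to 4.83; 0.742) and sample 6 for Slc22a7 (8.45, others 6.58 to 7.21; 0.664). Outside the genes compared, 163 of 6276 probe sets without exactly 1 symbol differed between the Western and control groups (101 higher, 62 lower; limma).

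For the Western-style diet against the control diet, 1 of 100 splits of the 11 samples, the real one, called as many genes (1180, highest other 1). This argues against chance for the gene count, as far as 100 splits can. As many lists passed in 3 of 100 (15, highest other 15), which argues against chance for the lists but does not exclude it. For the Western-style diet with quercetin against the control diet, 1 of 100 called as many genes (738, highest other 165), which argues against chance. As many lists passed in 16 of 100 (12, highest other 14), so chance is not excluded for these lists. For quercetin within the Western-style diet, 62 of 100 passed as many lists (3, highest other 13), so chance is not excluded for them. All 100 of 100 called as many genes (0, highest other 2), which a real count of 0 makes certain and which says nothing on chance. Nor is it for the opposition, where 21 of 100 relabellings gave a covariance as low (−0.013, lowest other −0.032). Splits that kept the samples numbered 1 to 3 and 4 to 6 apart led to the same verdicts. For the Western-style diet 1 of 100 called as many genes (highest other 1) and 4 of 100 passed as many lists (highest other 17). The split with 17 lists exchanged western 1, 3, 5 and 6 with control 2, 3, 4-5 and 6. For the Western-style diet with quercetin against the control diet 2 of 100 called as many genes (highest other 777, a split that exchanged all 5 control samples with 5 of the 6 quercetin samples, close to the real one mirrored) and 13 of 100 passed as many lists (highest other 15). The split with 15 lists exchanged quercetin 1, 2, 3 and 5 with control 1, 2, 3 and 6. Splits near the mirrored real one keep a part of the real difference, so they are not free of it. For quercetin within the Western-style diet 69 of 100 passed as many lists (highest other 14), and 29 of 100 relabellings gave a covariance as low (lowest other −0.038). With the sets of numbers as a block, 1 of its splits called 186 genes where the real one called 0. That was the highest of the splits drawn, and the median of the other splits was 0. Whether it reflects a further structure among these 12 samples was not tested.

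Samples numbered 1 to 3 differed from those numbered 4 to 6 within the groups in 890 genes (487 higher and 403 lower in 4 to 6; 9 against 8 samples). Chance is argued against, since 1 of 100 regroupings within the groups, the real one, called as many (highest other 368), and RNA integrity and brightness are as the whole cause, since 582 of the 890 genes stayed called with both 3'/5' ratios and the brightness as covariates. Cages that differ independently in each group are argued against by a mean correlation of the differences of 0.34 between groups (0.29 to 0.41 over the 3 pairs), reached by 1 of 100 regroupings (highest other 0.27). The time of day of the dissection may be behind it: 10 of 15 circadian clock genes were called (7 higher, 3 lower; Fisher's exact p = 2.95e-09), such as Ciart (1.57), Dbp (1.25) and Arntl (−0.65), picked after their values were seen, and 9 of 18 unfolded protein and amino acid response genes were called too. Fisher's test counts genes as independent, which genes measured in the same samples are not, so its p overstates the evidence. Processing days and food intake stay open, no biological explanation was tested, and the labels give no batch. Each set holds 3 arrays of a group, as many as the mice of a cage, but which mice shared a cage is not given.

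The control arrays were dimmer as deposited. The hybridisation controls were higher on the Western arrays by 0.20 (log2; 95% interval 0.070 to 0.32; exact p = 0.00433) and the median of the genes by 0.15 (exact p = 0.0216), a difference of −0.049 (95% interval −0.19 to 0.095; exact p = 0.444). This difference does not compare like scales. The median signal was dim, at a mean of 14.98 on control and 18.32 on Western arrays. The constant added before the log2 conversion shrinks such a shift. The hybridisation controls were bright (log2 9.99 and 10.16), where the constant hardly matters. So the difference cannot decide whether hybridisation or scanning brightness accounts for the whole shift. The poly-A controls, which pass through the same scan, were not higher (−0.088, 95% interval −0.28 to 0.10; exact p = 0.316). The sets of controls differ in direction, and the amount of poly-A control added to each sample is not given, so brightness cannot be told apart from a real difference in the RNA that the diet made.

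The interferon response list was lower with quercetin by camera. Chance is not excluded, since the exact permutation p of the per-mouse means was 0.957 after adjustment over the 25 lists. The number of splits would not have let a single list pass in that test. A single mouse is argued against, since the difference of −0.20 was −0.16 at its smallest (without quercetin 6) and −0.25 at its largest (without western 2) with 1 of the 12 mice left out, but it lay in 1 set of numbers: 0.0039 in samples 1 to 3 and −0.40 in samples 4 to 6 (exact p of their difference 0.045, 0.208 adjusted over the lists). Fewer macrophages could contribute: the macrophage list had a shift of −0.049 (a median of −0.24 without quercetin 2), and the interferon list lay −0.15 from it with a standard error of 0.18, so this cannot be told apart. The macrophage list too differed between the sets, by 0.18 in samples 1 to 3 and −0.28 in samples 4 to 6. An effect of quercetin itself, the biological explanation that the design names, stays open as well.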

How the results depend on the processing

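The plan had counted control arrays 4 and 5 as 2 samples. Averaging them was chosen after the arrays were seen, and the planned count then became an alternative. The tests with the samples numbered 1 to 3 and 4 to 6 as a block or apart, with the actin 3'/5' ratio as a covariate, and by exact permutation of per-mouse list means, over all mice or within the sets of numbers, were chosen only after the result was seen.

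For the Western-style diet against the control diet, where 1180 genes changed, the count was 3725 on the values as deposited, where the control arrays are dimmer. It was 417 at an adjusted p under 0.01 and 436 with a fold of at least 1.5, which are stricter thresholds. It was 88 within the samples numbered 1 to 3 and 296 within those numbered 4 to 6, which are fewer samples. Leaving out 1 sample gave 748 (without western 4) to 1394 (without western 2), with 773 without control 6 and 784 without western 5. The other alternatives gave 1057 (no filter on dim genes) to 1646 (array weights), among them 1424 with control 4 and 5 as 2 samples, 1524 with the numbers 1 to 3 and 4 to 6 as a block and 1143 with a block for each number. It was 223 with the actin 3'/5' ratio as a covariate, where the median standard error was 0.142 in place of 0.116 and the 1180 genes kept a median of 90.0% of their change. Of the 1180 genes, 833 were called as deposited, 878 with array medians centred, 902 with the mean of a gene's probe sets, 958 with the block for each number and 1047 with a pseudocount of 1, all with the same sign.

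For the Western-style diet with quercetin against the control diet, where 738 genes changed, the count was 3255 as deposited, 263 at an adjusted p under 0.01 and 294 with a fold of at least 1.5. It was 224 and 32 within the samples numbered 1 to 3 and 4 to 6. It was 155 with the actin 3'/5' ratio as a covariate, where the median standard error was 0.139 in place of 0.116 and the 738 genes kept a median of 91.7% of their change. With only the 2 groups compared it was 466, a fit to fewer samples. Leaving out 1 sample gave 460 (without control 6) to 949 (without quercetin 6), with 479 without quercetin 2 and 481 without quercetin 5. The other alternatives gave 655 (pseudocount of 1) to 1039 (the numbers as a block). Of the 738 genes, 526 were called as deposited and 530 with array medians centred, all with the same sign. For quercetin within the Western-style diet limma called 0 genes under each alternative and without each sample, and 316 genes had an unadjusted p under 0.05 as deposited, 383 with medians centred, 400 within the samples numbered 1 to 3 and 1046 within those numbered 4 to 6.

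Lists passing camera numbered 15, 3 and 12 in the 3 comparisons (Western-style diet, quercetin within it, and Western-style diet with quercetin against the control diet). With an estimated correlation they numbered 1, 0 and 2, since the test then allows for genes of a list moving together. Exact permutation of per-mouse means, over all mice or within the sets of numbers, passed 0 for quercetin within the Western-style diet. The possible splits were too few for a single list to pass after adjustment, so this 0 says little. Leaving out 1 sample gave 13 to 16, 1 (without quercetin 6) to 8 (without quercetin 2) and 9 to 13, and the cause was not tested. With the numbers 1 to 3 and 4 to 6 as a block, and with a block for each number, 19 lists passed for the Western-style diet (12 higher, 7 lower). They gained fatty acid synthesis (adjusted p = 0.0328 and 0.0309), drug metabolism (0.0454 and 0.0386), male-biased (0.0454 and 0.0377) and female-biased genes (0.0468 and 0.0275). Drug metabolism also passed with only the 2 groups compared (0.0431), female-biased genes with the mean of a gene's probe sets (0.0409) and fatty acid synthesis with no filter on dim genes (0.0403). These lists also passed without 1 sample: fatty acid synthesis without control 1, control 2, western 4 or western 6 (lowest adjusted p = 0.0129), drug metabolism without control 6 (0.0357), male-biased genes without control 1, control 2 or western 6 (lowest 0.0185) and female-biased genes without control 3, control 6 or western 1 (lowest 0.0144). At the 50th percentile filter 3 lists, the markers of T cells, B cells and neutrophils, had too few members and gave no value. The opposition of the quercetin change to the diet change, −0.10 over all samples, was −0.22 without western 2 to 0.00089 without quercetin 6, and −0.19 with a block for each number. The cause of these shifts was not tested.

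Among named genes, Mvk differed by −0.43 between the Western and control groups (adjusted p = 0.021), but by −0.16 as deposited (0.4), −0.31 with medians centred (0.107) and −0.41 without control 2 (0.0528). Mx1 differed by 0.32 (adjusted p = 0.0382), with 0.0566 under an intensity trend, 0.0634 with only the 2 groups compared and up to 0.0988 without control 6. The cause was not tested. No called result passed in the opposite direction, but the acute phase list, called higher for the Western-style diet, had a median of −0.016 relative to all genes as deposited and with medians centred, where it did not pass. Values that pass neither way were not counted as reversed. Apart from leaving out samples, such sign changes numbered 22 of 1986 gene values for the Western-style diet, 46 of 2091 for quercetin within it and 0 of 274 for the Western-style diet with quercetin against the control diet, and for lists 1 of 331, 12 of 391 and 7 of 343. With samples left out they numbered 24 of 2424, 151 of 2601 and 0 of 324 gene values, and 1 of 403, 42 of 411 and 10 of 411 list values.

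The replicate numbers were checked for pairing: samples of the same number in different groups correlated at a median of 0.13 (13 of 16 above 0.1, lowest −0.26), against −0.024 for other numbers, and they were not taken to pair the samples. Genes left out as dim, 4548 of 18193, are those with the lowest mean signal, and changes in them were not tested in the main setting.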
